A study of Homo sapiens with 36 samples.

How the data were processed

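RNA was measured by bulk sequencing of poly(A)-selected, directionally prepared libraries, per the labels' protocols, in 36 tissue pieces from 18 patients with kidney cancer. Each patient gave 1 piece of clear cell renal cell carcinoma (ccRCC), the commonest kidney cancer, taken from the primary tumour, and 1 piece of the kidney beside it. The patient number shared by both labels gave the pairing.

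The deposited file held 1 table with 60521 genes, each with an Ensembl identifier, a symbol and a gene type. Its values are log2 of read counts scaled to a fixed total of reads assigned to genes (log2 CPM), as the authors deposited them, to 2 decimals. No pseudocount had been added, since 84.0% of low values in adjacent kidney and 83.9% in tumour lay on log2 of whole multiples of 1 step, and every value with a CPM of 1 or less was listed at 0. The submitters' processing notes name STAR 2.7.3, HTSeq 0.6.1 and DESeq2 1.14.1, and the builds hg19 and GRCh38, with no role or order, so which step used which was not given in the sources used here. The table gave no coordinates. Positions printed in the report come from GENCODE release 29 on GRCh38, matched by Ensembl identifier, which held 58306 of the 60521 identifiers.

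The depth of each library was estimated from the step between its values below 12 CPM. A value counted as whole when it lay within a relative distance of 0.0035 of a multiple of the step. On average 84.0% of low values were whole in adjacent kidney and 83.9% in tumour, so reads could not be recovered for nearly all genes. No count test was therefore run, apart from an alternative with voom weights. That alternative rebuilt approximate counts from CPM and estimated depth, with every value listed at 0 taken as 0 reads. Its values for genes at the floor thus depend on library depth. Reads that map to several genes appeared to have been shared or repeated between near-identical genes, as the mitochondrial genes and their nuclear copies carried like values, so such genes are given as uncertain. Low genes are measured with few reads: 1 read was worth 0.605 CPM on average in adjacent kidney and 0.139 CPM in tumour.

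Tumour was compared with adjacent kidney with limma 3.58.1 in R 4.3.3, on the deposited log2 CPM values, with patient as a fixed block and tissue as the tested term. Moderated variances followed a mean-variance trend, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A size limit of 2-fold, a log2 difference of 1, was applied for a further count. The filter fixed before the data were examined asked for a log2 CPM of at least 0 in 18 of the 36 libraries. Because every low value is listed at 0, that rule removes no gene, so it was read as above 0 in at least 18 libraries, which left 22049 genes, of which 15542 were protein coding and 3944 were lncRNA. A log2 difference of a gene near the floor can understate its change. Because depth differed between the tissues, it can also be too large, as 1 read was worth up to 1.92 CPM in the shallowest library.

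Gene lists, the rule for named genes, the design and most alternatives were chosen before the data were examined. There were 33 lists, of which 19 held pathways and 14 held cell type, tissue or handling markers. Lists were tested with camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 32 lists with at least 3 tested genes. Camera compares a list with all other genes. Beside it, camera with an estimated correlation and fry were run, and fry tests a list against no change. The pair differences of each list mean were also tested by a sign-flip permutation test with 100000 resamples, whose smallest possible p is 1e-05. Relations between list means across the 18 tumours were given as Pearson's r and Spearman's rho with two-sided permutation p-values from 100000 resamples, adjusted over 8 relations.

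Named genes are the 10 largest rises and the 10 largest falls past the threshold with a mean log2 CPM of at least 1 and the same direction in all 18 pairs, leaving out uncharacterised loci and sex-linked and receptor segment genes. They also include, in each list, up to 3 members with the largest rise and up to 3 with the largest fall past the threshold, and a fixed set of genes of glycosaminoglycan synthesis, lipoprotein uptake, ferroptosis and hypoxia. These parts named 175 genes, some of which are not reported here.

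Patients were kept as a block because both libraries of a pair come from 1 donor. The deviations of libraries from their group means correlated with a mean r of 0.0784 within a patient (range -0.193 to 0.518) and -0.0015 between patients, and 3 of 18 adjacent kidney libraries correlated best with the tumour of their own patient. In a check for mixed-up samples from sex-linked genes, 2 pairs had libraries on different sides of a fixed level, and 0 pairs differed when each library was read by the larger of the opposed signals, a reading chosen after the first count was seen. No library repeated another: the highest correlation between libraries was 0.964, and at most 9.50% of tested genes had identical values in any 2 libraries.

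The main script was tested on simulated values for the comparison of tumour with adjacent kidney over 22049 genes. Of 50 genes changed at each size, it recovered 12% at a log2 difference of 0.5, 60% at 1, 98% at 2 and 100% at 3, with 8 false calls, 5.59% of all calls. Of 20 unchanged lists 0 were called, and of 5 changed lists 5 were called. The simulated genes varied independently of each other, and no general shift between the tissues was built in. In the real lists the estimated correlation between genes reached 0.77, for mitochondrial genome transcripts. The simulation therefore cannot show how reliable list calls are when genes are correlated.

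Alternatives fixed beforehand were the fit with no replicate block, patient as a random effect, no filter, a stricter filter of log2 CPM of at least 2 in 18 libraries, median centring, quantile normalization, log2(CPM + 1), no variance trend, array weights, an exact signed-rank test, an adjusted p threshold of 0.01, limma's treat against 2-fold, leaving out each pair, and for the relations medians over members, z-scored members and differences within pairs. Added after seeing the data were a fit without 7 pairs holding a library under 2 M (mega) estimated reads, a fit without 3 doubted pairs, CPM recomputed without mitochondrial genes and 394 nuclear copies, and voom weights. A doubted pair is one where CA9 was not at least 2-fold higher, or UMOD not at least 2-fold lower, in the tumour library. Further tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Haemoglobin genes are not analysed here, and the red blood cell list, with 3 of 7 genes in the table and 0 tested, gave no result.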

Results

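The series asks how glycosaminoglycans, the sugar chains of proteoglycans, relate to lipoprotein uptake and to protection of tumours from ferroptosis, a form of cell death driven by lipid peroxidation. The patient data compare primary clear cell renal cell carcinoma (n = 18) with the kidney beside each tumour (n = 18). Estimated depth differed between the tissues. Adjacent kidney libraries held 3.24 ± 2.26 M reads assigned to genes (M, mega; SD, n = 18, range 0.520 to 7.90 M) and tumour libraries 8.58 ± 2.73 M (SD, n = 18, range 2.54 to 11.8 M). Transcripts of the mitochondrial genome and their nuclear copies took 17.98% ± 11.8 of the CPM in adjacent kidney and 4.71% ± 3.94 in tumour (SD, n = 18 each). The 10 most abundant genes of a library took 17.2% and 5.91%.

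**Figure D1:**
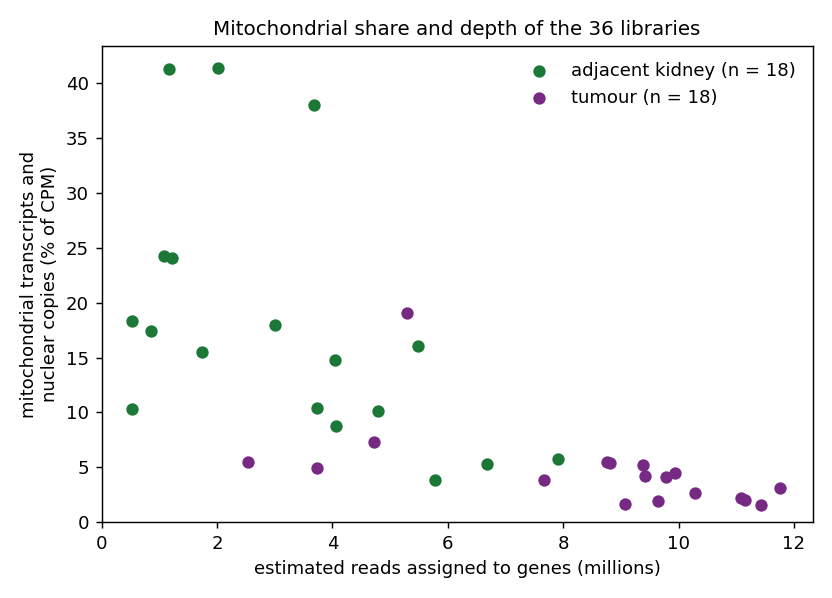
Share of CPM taken by mitochondrial transcripts and their nuclear copies (percent, y axis) against estimated reads assigned to genes (M reads, x axis), 1 point per library, green for adjacent kidney and purple for tumour. Adjacent kidney libraries reach 41.4%, and tumour libraries reach 19.1%.

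Tumour and adjacent kidney differed in many of the genes tested. Markers of nephron segments fell, with UMOD, the main protein of urine, lower by a log2 difference of 4.73 ± 0.52 (SE, 18 pairs). Hypoxia-response genes rose, with CA9, a carbonic anhydrase used as a marker of this cancer, at 2.84 ± 1.63 log2 CPM in adjacent kidney and 6.56 ± 1.44 in tumour (SD, n = 18 each). With limma, 12203 of 22049 genes passed an adjusted p of 0.05, of which 8614 were higher and 3589 lower in tumour. Without the 7 pairs holding a shallow library 6381 passed, and with voom weights on rebuilt counts 10443. At 2-fold or more there were 5292 genes, 3451 higher and 1841 lower, against 1399 and 3303 after median centring, 2167 and 2284 after quantile normalization, and 2240 and 2497 without mitochondrial genes. The split depends on scaling, because the median tested gene was itself 0.30 higher in tumour on the log2 scale, and the mean difference of the library medians was 0.39. Higher calls made up 70.6% of all calls on the deposited scale, 42.2% after median centring (4748 higher, 6517 lower), 53.8% after quantile normalization (6001 higher, 5159 lower) and 56.6% with CPM recomputed without mitochondrial genes and copies (6426 higher, 4920 lower). Across these 4 scalings, 4535 genes were called higher and 3461 lower in every one. Values called centred are relative to the library medians.

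The 10 named genes with the largest rise were higher in 18 of 18 pairs. MYOCOS had the largest, 4.20 ± 0.39 (SE) on the log2 scale, adjusted p = 6.17e-08. TNFAIP6, a secreted hyaluronan-binding protein, rose by 3.56, ENPP3, an ectonucleotidase, by 3.53, CD70, a ligand of the TNF family, by 3.52 and GABRD, a GABA receptor subunit, by 3.50. MIR210HG, the host transcript of a hypoxia-induced microRNA, rose by 3.42, CDCA2 by 3.29, DGCR5 by 3.26, FABP7, a fatty acid binding protein, by 3.25 and DOC2A by 3.21. The 10 with the largest fall were lower in 18 of 18 pairs. CRYAA and CRYAA2, near-identical crystallin genes whose reads cannot be told apart, fell by 5.35 and 5.33. SFRP1, a secreted WNT antagonist, fell by 5.12, GGT6 by 4.80, UMOD by 4.73, HPD, an enzyme of tyrosine breakdown, by 4.54, KNG1, kininogen, by 4.47, DUSP9 by 4.44 and SLC12A1, the salt transporter of the loop of Henle, by 4.39. All 20 kept their direction and call under the 4 scalings.

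Hypoxia targets and glycolysis enzymes rose together. In this list 29 of 32 genes rose and 0 fell, counted over all genes and likewise adjusted over the list alone, and after median centring 26 rose and 2 fell. The list mean was 5.12 ± 0.56 log2 CPM in adjacent kidney and 6.88 ± 0.47 in tumour (SD, n = 18 each) and was higher in 18 of 18 pairs. STC2, stanniocalcin, rose by 3.80, CA9 by 3.72 (higher in 16 of 18 pairs), HK2, hexokinase, by 3.07 and VEGFA, the angiogenic growth factor, by 1.43. In the doubted pairs 7 and 16 CA9 was lower in tumour, at 6.92 against 7.18 and at 1.82 against 4.04 log2 CPM. CA9 (ENSG00000107159) lies on chromosome 9 from 35673856 to 35681159 (GRCh38). Camera gave an adjusted p of 4.25e-10 with the preset correlation, against an adjusted p = 0.270 with an estimated correlation.

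Genes that build chondroitin and dermatan sulfate rose in tumour. Of 16 tested genes 11 rose and 0 fell over all genes, and 12 rose and 0 fell adjusted over the list alone. CHST13, CHST15 and CHST11, sulfotransferases of chondroitin, rose by 2.40, 2.08 and 1.83, and CHSY1 and CHPF, which extend the chain, by 1.59 and 1.05. CSGALNACT1, which starts the chain, rose by 0.70, but its centred difference was 0.32 (adjusted p = 0.23), and its call was lost without the doubted pairs (0.0975). CHST11 (ENSG00000171310) lies on chromosome 12 from 104455295 to 104762014 and CHSY1 (ENSG00000131873) on chromosome 15 from 101175723 to 101251932 (GRCh38). The list mean rose by 1.01 (17 of 18 pairs higher), and its centred mean was 0.62, with 9 genes higher and 1 lower after centring and 7 higher without the shallow pairs. By camera the adjusted p was 0.0229, against an adjusted p = 0.602 with an estimated correlation, and the call was lost under the stricter filter (adjusted p = 0.0952). Endothelial and macrophage markers, given further on, were also higher in tumour.

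Among genes for the shared linker and the sugar and sulfate donors, 12 of 21 rose, 1 fell and 8 did not pass over all genes, the same numbers as adjusted over the list alone, and after centring 8 rose and 2 fell. SLC35A2, a UDP-galactose transporter, rose by 1.33, SLC35B2, the transporter of the sulfate donor, by 1.23, PXYLP1, a xylose phosphatase, by 1.13 and XYLT2, which adds the first xylose, by 0.92. UGDH, which makes UDP-glucuronic acid, fell by 1.32 (15 of 18 pairs lower). B4GALT7, B3GALT6 and B3GAT3, which complete the linker, rose by 0.63, 0.79 and 0.59, with centred differences of 0.24, 0.41 and 0.20, of which those of B4GALT7 and B3GAT3 did not pass (adjusted p = 0.12 and 0.21), while that of B3GALT6 did not after quantile normalization (0.0583). XYLT1, UXS1 and PAPSS1 did not pass, at 0.35, 0.46 and 0.44. The list mean difference was 0.54 and camera's adjusted p 0.0585, against an adjusted p = 0.627 with an estimated correlation. Without the 7 pairs holding a shallow library, 2 genes were called higher and 0 lower, and UGDH was at -0.58 (adjusted p = 0.131).

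Heparan sulfate genes moved both ways. Of 16 synthesis genes 9 rose and 4 fell over all genes and also adjusted over the list alone, and after centring 6 rose and 5 fell. HS3ST2 rose by 1.77, NDST1, which starts sulfation, by 1.30, HS2ST1 by 1.24, and the chain polymerases EXT2 and EXT1 by 1.12 and 0.82, the last with a centred difference of 0.44 (adjusted p = 0.082) and a difference of 0.19 (adjusted p = 0.653) without the shallow pairs. HS3ST3A1, HS6ST2 and HS6ST3 fell by 2.25, 1.77 and 1.21. Camera gave an adjusted p of 0.880 for the list. Among heparan sulfate proteoglycans 6 of 14 rose and 2 fell over all genes and adjusted over the list alone, after centring 5 and 3, with an adjusted p of 0.716. HSPG2, perlecan, rose by 1.94, SDC3 by 1.41 and AGRN by 1.06, while GPC3 and GPC5 fell by 2.58 and 1.85. SDC1 and SDC4, syndecans, differed by 0.17 and -0.04 and did not pass, although SDC4 passed after centring at -0.43. Among chondroitin or dermatan sulfate proteoglycans 7 of 18 rose and 3 fell over all genes and adjusted over the list alone, after centring 4 and 5, with an adjusted p of 0.952. The mean of that list was 0.34 and the median 0.16, while camera placed it lower than other genes. ACAN rose by 2.73, ESM1 by 2.60, CSPG4 by 2.11 and VCAN by 1.27, the last not past the threshold after centring (adjusted p = 0.060), while DCN, decorin, fell by 3.21, SPOCK1 by 1.24 and TGFBR3 by 0.87. Among enzymes that trim or break down these chains 16 of 21 rose and 0 fell over all genes, 17 rose adjusted over the list alone, and after centring 11 rose and 1 fell. GALNS, CEMIP2 and SGSH rose by 1.40, 1.34 and 1.29. The list test by camera gave an adjusted p of 0.00584, against an adjusted p = 0.602 with an estimated correlation. Without the 7 shallow pairs 5 of these 21 were called higher, and 1 of the 14 heparan sulfate proteoglycans.

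**Figure D2:**
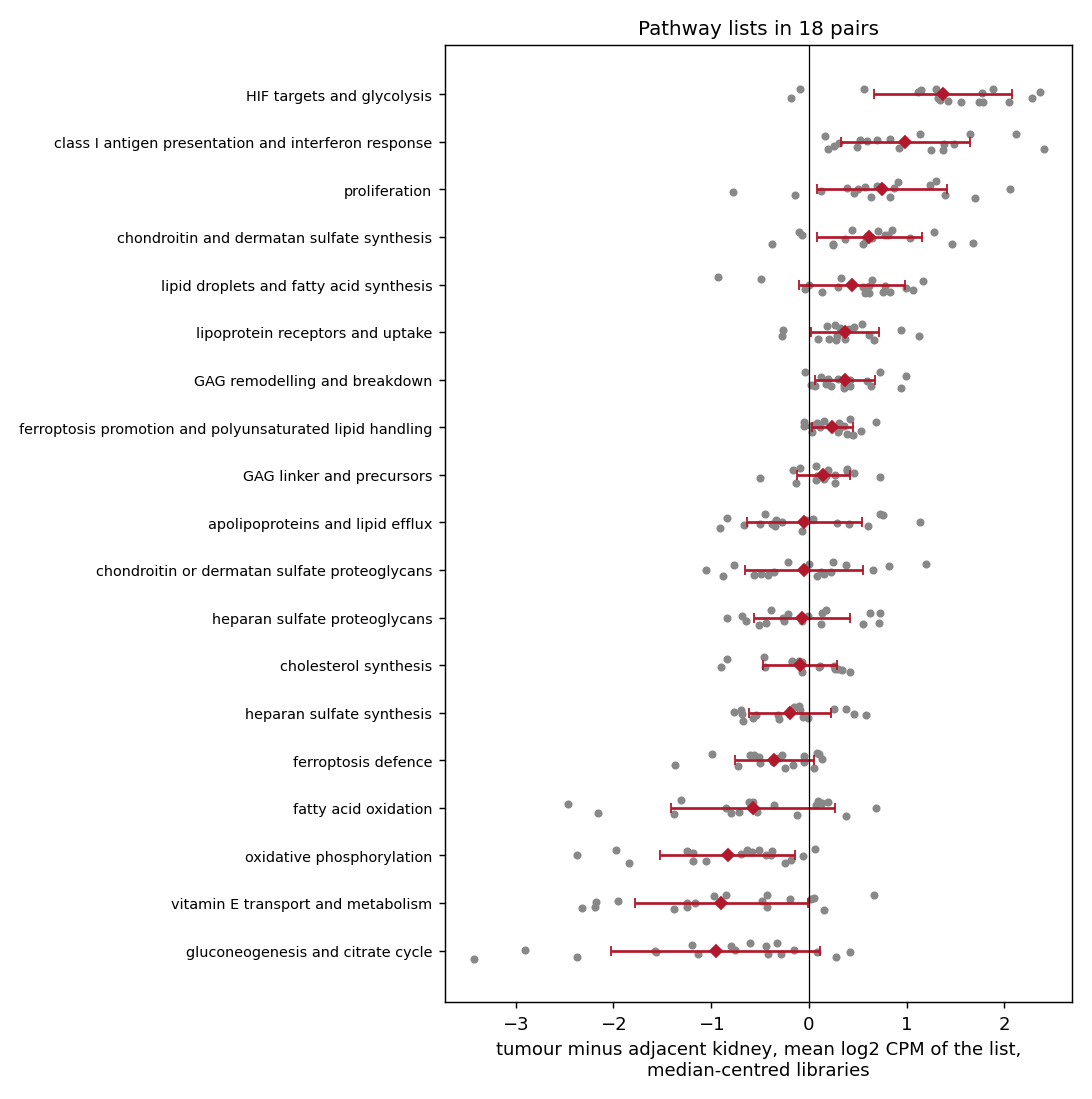
Tumour minus adjacent kidney difference of the mean log2 CPM of each pathway list after median centring (x axis), 1 row per list, 1 grey point per pair (n = 18), with the mean and SD in red. The chondroitin and dermatan sulfate synthesis list has a mean of 0.62, and the ferroptosis defence list -0.35.

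Several lipoprotein receptors rose in tumour. SCARB1, the HDL receptor, was 4.69 ± 1.01 log2 CPM in adjacent kidney and 7.49 ± 0.89 in tumour (SD, n = 18 each), a rise of 2.80 seen in 18 of 18 pairs (limma adjusted p = 7.36e-08). CD36, a scavenger receptor, rose by 2.23, STAB1 by 1.81, VLDLR by 1.28 and LRP1 by 1.27. LRP2, megalin, rose by 0.73, but its centred difference was 0.35 (adjusted p = 0.38). SCARB1 (ENSG00000073060) lies on chromosome 12 from 124776856 to 124882668 (GRCh38). In the list 15 of 27 genes rose and 2 fell over all genes and adjusted over the list alone, and after centring 11 rose and 3 fell. In camera the list had an adjusted p of 0.0728, and after median centring it was 0.0193, against an adjusted p = 0.624 with an estimated correlation on the deposited scale. Macrophage and endothelial markers were also higher in tumour, with list mean differences of 1.45 and 1.10.

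Among apolipoproteins and lipid efflux genes 5 of 13 rose and 4 fell over all genes, 6 and 4 adjusted over the list alone, and 4 and 4 after centring. The cholesterol exporters ABCG1 and ABCA1 rose by 2.17 and 1.89 and APOC1 by 1.71, while APOD, APOH and MTTP, which loads lipid onto lipoproteins, fell by 1.61, 1.50 and 1.10. Camera gave an adjusted p of 0.840. Lipid droplet and fatty acid synthesis genes rose, 12 of 17 with 2 falls over all genes and adjusted over the list alone, and 9 with 3 falls after centring. FABP7 and FABP6 rose by 3.25 and 2.96, HILPDA, an inhibitor of lipolysis, by 1.90 and PLIN2, the droplet coat protein, by 1.30, while G0S2 and PLIN4 fell by 1.58 and 1.42. Camera's adjusted p was 0.0403, against an adjusted p = 0.561 with an estimated correlation. This call was lost when pair 1, 2, 3, 6, 8 or 12 was left out, with adjusted p-values from 0.0501 to 0.0556, and under the stricter filter (0.125). In cholesterol synthesis 7 of 19 rose and 1 fell over all genes, 6 and 1 adjusted over the list alone, and 2 and 4 after centring, with an adjusted p of 0.694. LSS and NSDHL rose by 0.96 and 0.82, the latter not after quantile normalization (adjusted p = 0.0564), PMVK fell by 0.52, and CYP51A1, listed near the floor at 0.36 log2 CPM in adjacent kidney, rose by 0.64 with a centred adjusted p of 0.40. Without the shallow pairs 2 cholesterol synthesis genes were called higher and 0 lower.

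Genes of ferroptosis defence moved in both directions. GPX4, the peroxidase that detoxifies lipid hydroperoxides, fell from 7.82 ± 0.51 to 7.08 ± 0.38 log2 CPM (SD, n = 18 each), a log2 difference of -0.74 with 15 of 18 pairs lower (limma adjusted p = 4.70e-04), a call lost without the shallow pairs (-0.38, adjusted p = 0.0905). FTL, the ferritin light chain, NQO1 and MBOAT2 fell by 1.35, 0.98 and 0.75. SCD, which makes monounsaturated fatty acids, rose by 2.22, HMOX1 by 1.10 and PDSS1 by 0.71, the last not after centring (adjusted p = 0.15). SLC7A11, the cystine importer, differed by 0.01 ± 0.36 (SE) and did not pass. It lay near the floor, at it in several libraries, and its highest adjacent kidney value, 4.26 log2 CPM, came from the shallowest library. AIFM2, also called FSP1, rose by 0.39 on the deposited scale, with a centred difference of 0.00 (-6e-04), and its call was lost with no replicate block for the pairs (adjusted p = 0.0686). Over all genes 7 of 31 rose and 8 fell, as adjusted over the list alone, and after centring 2 rose and 13 fell. The list mean was 0.03, its median -0.005 and camera placed it lower than other genes, with an adjusted p of 0.137. After median centring the mean was -0.35 (adjusted p = 0.0459), against an adjusted p = 0.624 with an estimated correlation on the deposited scale, and without the shallow pairs 4 genes were called higher and 5 lower. GPX4 (ENSG00000167468) lies on chromosome 19 from 1103926 to 1106791 (GRCh38).

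In the list of ferroptosis promotion and polyunsaturated lipid handling 13 of 22 rose and 2 fell over all genes and adjusted over the list alone, and 9 and 5 after centring. The lipoxygenases ALOX15B, ALOX5 and ALOX12 rose by 2.98, 2.57 and 1.58, and PEBP1 and CHAC1 fell by 1.08 and 0.98. ACSL4, which activates polyunsaturated fatty acids, differed by -0.09 and did not pass, and was lower after centring at -0.47 (adjusted p = 0.034). The list mean rose by 0.63 (17 of 18 pairs higher). Camera gave an adjusted p of 0.172 for the list, against an adjusted p = 0.627 with an estimated correlation, and without the shallow pairs 6 genes were called higher and 1 lower. The list was called with no filter (adjusted p = 6.98e-04) and, against no change, by the signed-rank test (6.20e-04) and fry (8.64e-04). Of 7 genes of vitamin E transport and metabolism 3 rose and 3 fell over all genes and adjusted over the list alone, and 2 and 3 after centring. AFM, a vitamin E carrier of plasma, CYP4F2, a vitamin E hydroxylase, and TTPA, the tocopherol transfer protein, fell by 3.09, 2.62 and 1.27. In most tumour libraries TTPA lay at the floor. SEC14L4 and SEC14L2 rose by 1.61 and 1.34, and TTPAL by 0.51, the last not after centring (adjusted p = 0.42). By camera the adjusted p was 0.334.

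**Figure D3:**
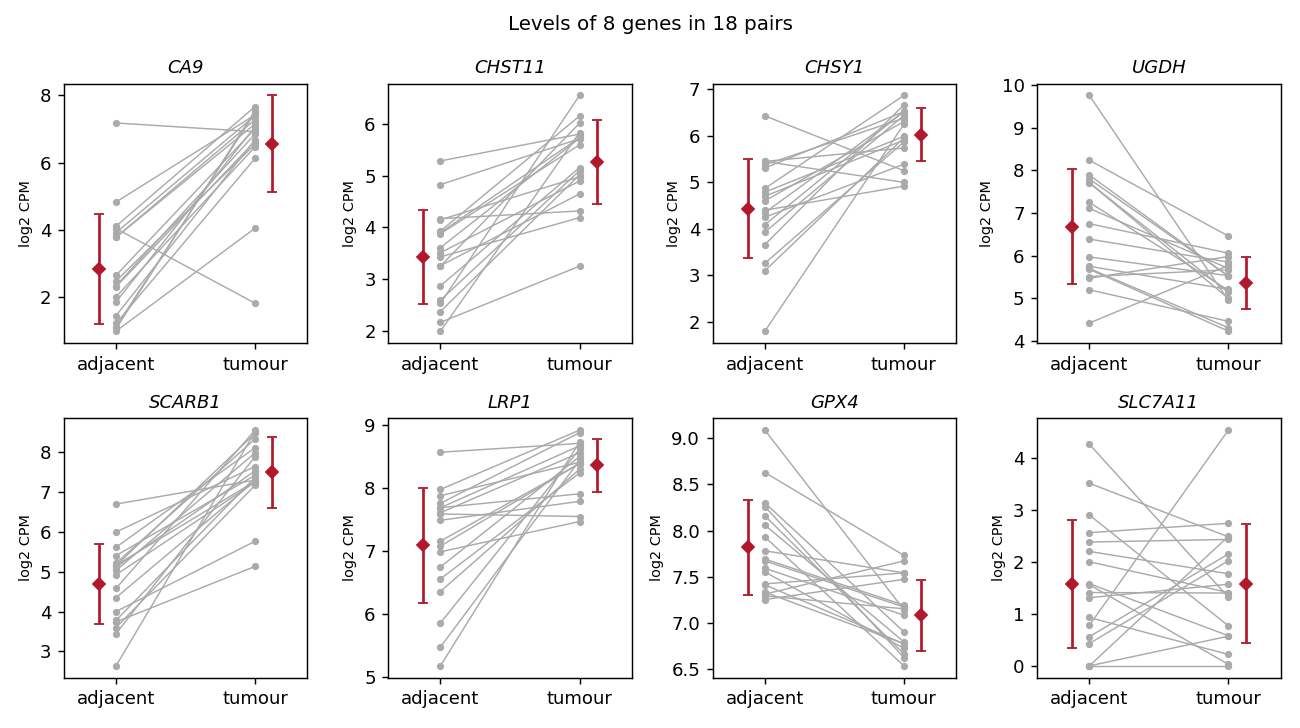
Levels in log2 CPM (y axis) of 8 genes in adjacent kidney and tumour, with grey lines joining the libraries of each pair (n = 18) and the mean and SD in red. SCARB1 is higher in tumour in 18 of 18 pairs, and GPX4 is lower in 15 of 18.

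Most genes of oxidative phosphorylation fell, as did a part of those of glucose production and fatty acid oxidation. In oxidative phosphorylation 18 of 23 nuclear genes fell and 1 rose over all genes and adjusted over the list alone, and after centring 20 fell and 1 rose. COX6C, UQCRFS1 and NDUFA4, subunits of the respiratory chain, fell by 0.99, 0.98 and 0.95. NDUFV2, listed near the floor at 0.63 log2 CPM in adjacent kidney, rose by 1.17. The list test by camera gave an adjusted p of 3.75e-08, against an adjusted p = 0.270 with an estimated correlation, and without the shallow pairs 7 genes were called lower and 1 higher. In gluconeogenesis and the citrate cycle 9 of 20 fell and 0 rose over all genes and adjusted over the list alone, and 13 fell after centring. PCK1 and FBP1, enzymes of glucose production, fell by 2.46 and 1.24. In camera the gluconeogenesis list had an adjusted p of 8.61e-04, against an adjusted p = 0.561 with an estimated correlation. Without the shallow pairs 4 of its genes were called lower and 1 higher, and the call of PCK1 was lost (adjusted p = 0.143). Proximal tubule markers were lower in the same tumours, with a list mean difference of -1.69 and 10 of 16 called lower. In fatty acid oxidation 5 of 21 fell and 1 rose over all genes, 4 and 0 adjusted over the list alone, and 10 and 0 after centring. ECHS1, HADH and ETFB fell by 1.21, 0.72 and 0.68, and ACADL rose by 0.93 on the deposited scale (centred adjusted p = 0.23). Camera's adjusted p was 0.0180, against an adjusted p = 0.602 with an estimated correlation, and without pair 1 it was 0.0529. The call was also lost without the shallow pairs (0.0757), without the doubted pairs (0.0757), with no filter (0.193), by the signed-rank test (0.396) and by fry (0.178). The list mean was lower in 9 of 18 pairs.

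Proliferation and antigen presentation genes rose. In the proliferation list 19 of 23 rose and 0 fell over all genes and adjusted over the list alone, and 15 rose and 1 fell after centring. MKI67, UBE2C and BIRC5, genes of dividing cells, rose by 1.85, 1.84 and 1.83. By camera the adjusted p was 4.74e-04, against an adjusted p = 0.561 with an estimated correlation. In class I antigen presentation and interferon response 19 of 20 rose and 0 fell over all genes, 20 rose adjusted over the list alone, and 16 rose and 0 fell after centring. TAP1, a peptide transporter, rose by 2.46, CXCL10, a chemokine, by 2.25, and HLA-B, whose reads may be shared with other class I genes, by 2.09. The list test by camera gave an adjusted p of 9.33e-06, against an adjusted p = 0.561 with an estimated correlation. T and NK cell markers and macrophage markers were also higher in tumour, with list mean differences of 1.38 and 1.45.

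Kidney cell markers fell in tumour and several blood and vessel markers rose. All 11 markers of the loop of Henle and distal tubule fell, over all genes, adjusted over the list alone and after centring, with TMEM52B, CALB1 and SLC12A3 lower by 5.30, 5.10 and 4.96. In camera the list had an adjusted p of 3.67e-12, against an adjusted p = 0.152 with an estimated correlation. In the collecting duct 13 of 14 fell and 0 rose over all genes, adjusted over the list alone and after centring, with AQP2 and FOXI1 lower by 4.88 and 4.30 (camera adjusted p = 2.94e-10). For it the test gave an adjusted p = 0.182 with an estimated correlation. The tumour library of pair 12 stood apart, with a collecting duct mean of 6.79 log2 CPM against 5.52 in its adjacent kidney and at most 2.48 in the other tumours. Its loop and podocyte means, 7.30 and 7.85, also lay above those of the other tumours, at most 2.84 and 4.31. This is 1 of the 3 doubted pairs, without which 11 collecting duct markers were called lower and 1 higher. Of 8 podocyte markers 6 fell and 1 rose over all genes and adjusted over the list alone, and 6 and 0 after centring. NPHS1, nephrin, fell by 6.10 and WT1 by 3.08, while SYNPO rose by 0.65, with a centred adjusted p of 0.27. Camera's adjusted p for podocytes was 8.66e-06, against an adjusted p = 0.270 with an estimated correlation. Of 16 proximal tubule markers 10 fell and 2 rose over all genes and adjusted over the list alone, and 11 and 0 after centring. SLC22A8, SLC34A1 and SLC36A2 fell by 4.17, 3.89 and 3.81, while SLC17A3 and SLC22A2 rose by 1.38 and 0.87 on the deposited scale (centred adjusted p = 0.081 and 0.089). Camera's adjusted p for the proximal tubule was 1.20e-05, against an adjusted p = 0.354 with an estimated correlation, and without the shallow pairs 6 genes were called lower and 2 higher. The transcripts of the mitochondrial genome fell, 11 of 11 over all genes and adjusted over the list alone and 10 of 11 after centring. MT-ND1, MT-CO2 and MT-CO1, which have nuclear copies, fell by 2.36, 2.13 and 1.84, the last with a centred adjusted p of 0.053. After quantile normalization MT-ND1 was at -1.38, and MT-CO1 at -0.25 (adjusted p = 0.61). Camera's adjusted p was 9.24e-09, against an adjusted p = 0.270 with an estimated correlation.

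Endothelial markers rose, 10 of 13 with 1 fall over all genes and adjusted over the list alone, and 9 and 1 after centring. VWF, PLVAP and TIE1 rose by 2.38, 2.04 and 1.72, and EMCN fell by 1.35. By camera the adjusted p was 0.0390, against an adjusted p = 0.627 with an estimated correlation. The call was lost when pair 1, 3, 8, 9 or 18 was left out (adjusted p from 0.0501 to 0.0532), under the stricter filter (0.123) and without the shallow pairs (0.0744). Of 13 macrophage markers 10 rose and 0 fell over all genes and adjusted over the list alone, and 9 and 1 after centring. TREM2 and FCGR3A, the latter near-identical to FCGR3B, each rose by 3.01, and LYZ by 2.39. The list test by camera gave an adjusted p of 0.00685, against an adjusted p = 0.602 with an estimated correlation. Of 18 T and NK cell markers 14 rose and 0 fell over all genes, 16 rose adjusted over the list alone and 10 after centring, led by NKG7, PRF1 and GNLY at 2.14, 2.11 and 2.11. In camera the list had an adjusted p of 0.00266, against an adjusted p = 0.602 with an estimated correlation, and without the shallow pairs 8 genes were called higher. B and plasma cell markers went the other way, with 3 of 7 lower and 0 higher over all genes and adjusted over the list alone, and 4 lower after centring. MS4A1 and POU2AF1 fell by 2.17 and 1.36. Camera's adjusted p was 0.0348, against an adjusted p = 0.602 with an estimated correlation, and the call was lost without pair 2, 8 or 13 (adjusted p = 0.0638, 0.0501 and 0.0562). It was also lost after median centring (0.100), after quantile normalization (0.0926), without mitochondrial genes (0.0646), with no filter (0.275), under the stricter filter (0.152), with patient as a random effect (0.0649), by the signed-rank test (0.181) and by fry (0.126). Without the shallow pairs 0 of its genes were called.

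Of 10 neutrophil and mast cell markers 7 rose and 0 fell over all genes and adjusted over the list alone, and 3 and 0 after centring, with an adjusted p of 0.174 and 2 genes called higher without the shallow pairs. This list was called after median centring (adjusted p = 0.0488), after quantile normalization (0.0479), with no filter (0.00313) and, against no change, by the signed-rank test (0.00393) and fry (0.00228), and not with an estimated correlation (0.627). CSF3R, a cytokine receptor, and TPSAB1, a tryptase with near-identical copies, rose by 2.48 and 1.53. Fibroblast and pericyte markers moved both ways, 5 of 14 higher and 2 lower over all genes and adjusted over the list alone, and 2 and 3 after centring, with an adjusted p of 0.880. Without the shallow pairs 1 was called higher and 2 lower. RGS5, a pericyte gene, rose by 2.06, COL5A1 by 1.35 and COL1A1 by 1.01, the last with a centred adjusted p of 0.098 and 0.0542 without the doubted pairs, while PDGFRA and LUM fell by 2.48 and 2.24. Of 4 tested adrenal cortex genes 1 rose and 3 fell over all genes, adjusted over the list alone and after centring. CYP21A2, which has a near-identical pseudogene, rose by 1.44, and CYP17A1, STAR and CYP11A1 fell by 1.91, 1.36 and 1.03 (camera adjusted p = 0.0666, and 0.0467 without pair 14). In this list 1 gene was called higher and 2 lower without the shallow pairs, where STAR was at -0.63 (limma adjusted p = 0.184). Of 15 immediate early and heat shock genes, signs of tissue handling, 2 rose and 4 fell over all genes, 2 and 2 adjusted over the list alone, and 1 and 5 after centring. HSPA6 rose by 2.62 and JUN by 0.47, the latter with a centred adjusted p of 0.71, while EGR1, ATF3 and HSPB1 fell by 0.78, 0.59 and 0.49. The call of ATF3 was lost with no replicate block for the pairs (adjusted p = 0.123) and without the doubted pairs (0.0709). The list mean was 0.08, the median -0.04 and camera's direction was lower, with an adjusted p of 0.218 and, without the shallow pairs, 1 gene called higher and 0 lower.

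**Figure D4:**
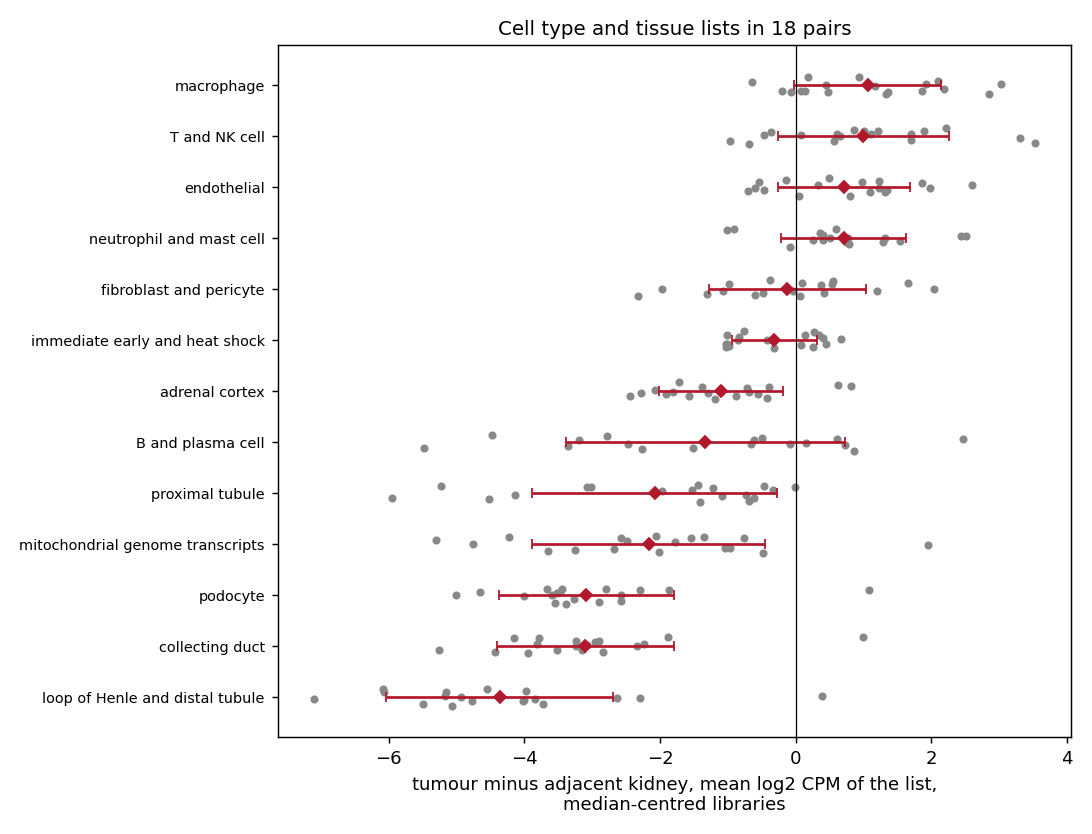
Tumour minus adjacent kidney difference of the mean log2 CPM of each cell type, tissue or handling list after median centring (x axis), 1 row per list, 1 grey point per pair (n = 18), with the mean and SD in red. The loop of Henle and distal tubule list has a mean of -4.36, and the macrophage list 1.06.

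The remaining comparison asks whether list levels followed each other from tumour to tumour (n = 18). Tumours with higher chondroitin and dermatan sulfate synthesis genes had higher fibroblast and pericyte markers, with r = 0.73 (permutation p = 6.6e-04, adjusted 0.00528) and rho = 0.58 (p = 0.0125, adjusted 0.0498). Without the 2 tumours farthest from the median r was 0.54 (p = 0.0319). Proximal tubule markers were lower in those tumours, with r = -0.56 (p = 0.0167, adjusted 0.0335), rho = -0.61 (p = 0.00873, adjusted 0.0498) and r = -0.58 (p = 0.0191) without 2 tumours. This relation did not pass with medians over members (r = -0.45, adjusted p = 0.0836) or with z-scored members (-0.48, 0.0851). Nor did it pass with differences within pairs (-0.41, 0.0958) or minus the library median (-0.55, 0.0585, and -0.52, 0.0531 for differences within pairs). It was stronger without the tumour libraries under 5 M reads (-0.71, 0.0116) and without the doubted tumours (-0.70, 0.0142). In both settings the relation with fibroblast and pericyte markers had r = 0.85. The synthesis list also followed endothelial markers (r = 0.59, p = 0.00976, adjusted 0.0335, rho = 0.53, p = 0.0259, adjusted 0.0624) and lipoprotein receptors (r = 0.57, p = 0.0148, adjusted 0.0335, rho = 0.45, p = 0.0617, adjusted 0.0822). In the tumour list means both were weaker without the 2 farthest tumours, where r was 0.38 (p = 0.143) and 0.32 (p = 0.231). With z-scored members, and without the 2 farthest tumours on that measure, these relations had r = 0.50 (p = 0.0498) and 0.47 (p = 0.0659). In differences within pairs they were r = 0.85 and 0.86 (adjusted p = 4e-05 each), and 0.68 (p = 0.00362) and 0.74 (p = 0.00144) without the 2 farthest pairs. Minus the library median neither passed in tumours (r = 0.54, adjusted p = 0.0585, and r = 0.31, adjusted p = 0.348), and in differences within pairs endothelial markers passed (r = 0.71, adjusted p = 0.00296) and lipoprotein receptors did not (r = 0.52, adjusted p = 0.0531). The other 4 of the 8 relations did not pass in the tumour values. The synthesis list gave r = 0.27 (p = 0.279, adjusted 0.279, rho = 0.14, p = 0.574) with hypoxia targets, r = 0.37 (p = 0.131, adjusted 0.210, rho = 0.52, p = 0.0312) with proliferation and r = 0.30 (p = 0.221, adjusted 0.268, rho = 0.47, p = 0.0514) with macrophage markers. Lipoprotein receptors gave r = 0.29 (p = 0.235, adjusted 0.268, rho = 0.31, p = 0.214) with hypoxia targets. In differences within pairs, an alternative fixed beforehand, 3 of these 4 passed: the synthesis list with hypoxia targets (r = 0.51, adjusted p = 0.0413) and with macrophage markers (0.66, 0.00522), and lipoprotein receptors with hypoxia targets (0.61, 0.0125). With the library medians subtracted from these differences none of the 3 passed (r = 0.14, 0.33 and 0.46, adjusted p = 0.677, 0.232 and 0.0907). Macrophage markers also passed without the tumour libraries under 5 M reads (0.57, 0.0438). With the library median subtracted from each list mean, a setting added after seeing the data, 1 of the 8 relations passed, that with fibroblast and pericyte markers. It had r = 0.64 (adjusted permutation p = 0.0379) and rho = 0.58 (adjusted p = 0.0649). Without the 2 farthest tumours its r was 0.48 (p = 0.0586).

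**Figure D5:**
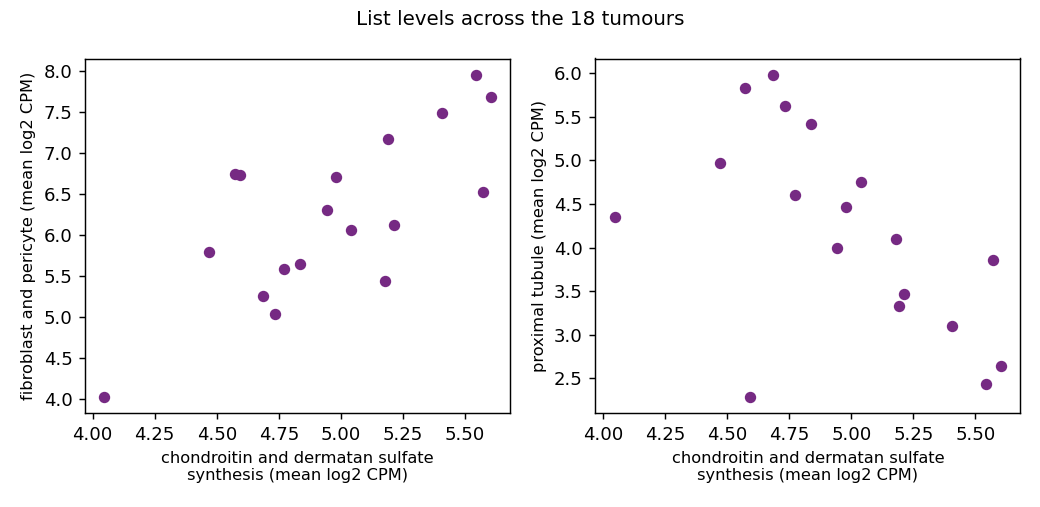
Mean log2 CPM of fibroblast and pericyte markers (left, y axis) and of proximal tubule markers (right, y axis) against mean log2 CPM of chondroitin and dermatan sulfate synthesis genes (x axis), 1 point per tumour (n = 18). The left panel has r = 0.73 and the right panel r = -0.56.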

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

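The fits without 7 shallow pairs, without 3 doubted pairs, without mitochondrial genes and with voom weights, and for the relations the settings without certain tumours or minus the library median, in tumours or within pairs, were chosen after seeing the data. The causes of the changes below were not tested, except that fewer pairs or genes were used where the setting says so. The paired fit and the fit with no replicate block gave 12203 and 11974 genes, 8614 and 8555 higher, 5292 and 5269 at 2-fold or more, and 18 called lists each. The block changed the call of ATF3 and AIFM2 among named genes and no call of a list. Leaving out each pair gave 11272 to 12932 genes and 4822 to 5887 at 2-fold or more.

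Genes differing between tumour and adjacent kidney numbered 6381 without the shallow pairs, 4195 higher and 2186 lower. Median centring gave 4748 higher and 6517 lower, and the stricter filter 2296 lower. Genes differing by at least 2-fold numbered 3486 without the shallow pairs, 2138 of them higher, and 753 with treat, 328 higher and 425 lower. The higher ones numbered 1399 after centring, 2167 after quantile normalization and 2240 without mitochondrial genes, and the lower ones 1075 under the stricter filter and 3303 after centring. Without the doubted pairs the counts were 11912 and 6185.

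Of 32 lists, 18 passed camera, 9 upward and 9 downward. With an estimated correlation camera in limma called 0, with 4 at an unadjusted p under 0.05, while fry called 22 by direction and 30 in either direction. Leaving out pairs gave 15 to 20 called lists. The chondroitin and dermatan sulfate synthesis mean was 1.004 and not called under the stricter filter, and 1.01 and not called with an estimated correlation. Ferroptosis defence was called lower than other genes under the stricter filter, where the list mean was 0.0354 and the median gene 0.41 (adjusted p = 0.0429), and with a mean below 0 after median centring (-0.35), quantile normalization (-0.28, 0.00507) and without mitochondrial genes (-0.20, 0.0400). Fry and the signed-rank test compare a list with no change, not with other genes, and after centring the GAG linker mean was 0.15 (camera adjusted p = 0.0537). The GAG linker list was called with no filter (0.54, 1.1e-05), by the exact signed-rank test (0.54, 0.0061) and by fry (0.54, 0.0039), and without pair 6, 14 or 15 (adjusted p = 0.0242, 0.0450 and 0.0434), with means from 0.45 to 0.63 over all pairs left out. Lipoprotein receptors were called with a random effect (0.75, 0.0468), no filter (0.71, 4.18e-05), centring (0.37), without the shallow pairs (0.72, 0.0384), with voom weights (0.66, 0.0345), by the signed-rank test (0.75, 1.22e-04) and by fry (0.75, 5.88e-04). Calls were also gained with no filter by cholesterol synthesis (0.0171) and heparan sulfate proteoglycans (0.0468), by the signed-rank test by adrenal cortex (0.00197), apolipoproteins (0.0193) and vitamin E genes (0.00957), and by fry by adrenal cortex (7.59e-04) and apolipoproteins (8.64e-04). Of the relations, 2 passed without the doubted tumours, 1 minus the library median, 6 in differences within pairs and 2 in such differences minus the library medians, against 4.

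AIFM2 went to 0.00 (-6e-04) after centring and -0.0311 after quantile normalization, neither called. Apart from pairs left out, named genes kept direction and call in 2305 results, lost the call in 116, gained it in 4 and turned in 2. Of the losses 39 came without the shallow pairs, among them GPX4, PCK1, ETFB, COX6C, MT-CO1, SYNPO, STAR, MS4A1, POU2AF1, TPSAB1, COL1A1, COL5A1, VCAN, AGRN, SDC3, XYLT2, B4GALT7, B3GALT6, B3GAT3, CSGALNACT1, CHPF, EXT1, UGDH, SLC35A2, SLC35B2, LSS, CYP51A1, PMVK, PDSS1, ALOX5, CHAC1, TTPAL, PLIN4, JUN, EGR1, ATF3 and HSPB1. Leaving out 1 pair ended the call of ATF3 in 8 cases, AIFM2 in 5, LRP2 in 9, CYP51A1 in 7, CSGALNACT1 and POU2AF1 in 6 each, ACADL in 4 and PLIN4 in 1, and gave one to UXS1 and PAPSS1 in 1 each. Depth limits the low genes, since 1 read was worth up to 1.92 CPM in the shallowest library.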

Other observations

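All tests of explanations below were chosen after the result was seen, except the regression on marker lists, whose bound was written before its result. The labels flipped within pairs gave at most 7 genes in 99 other draws, both for genes differing and for genes differing by at least 2-fold, against 12203 and 5292 for the real labels. Only 1 of the 100 splits, the real one, reached either count, the smallest share that 100 splits can give. Flipped pairs put the tissue difference into the residual spread, so such splits call few genes whenever the tissues differ. The splits thus argue against chance for a difference between the tissues as a whole, and do not bear on the size of either count.

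Proximal tubule genes did not move as a block. SLC17A3 and SLC22A2, carriers of that segment, and LRP2, its endocytic receptor, were higher in tumour by 1.38 ± 0.44, 0.87 ± 0.23 and 0.73 ± 0.29 on the log2 scale (SE, 18 pairs), while SLC22A8 fell from 5.77 ± 1.07 to 1.59 ± 1.90. After median centring these 3 differences did not pass the threshold. Genes linked to fibroblasts and pericytes parted as well: DCN, PDGFRA and LUM fell by 3.21, 2.48 and 2.24, while RGS5, a pericyte gene, rose by 2.06.

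The first pattern is that the median tested gene was higher in tumour, by 0.387 ± 0.111 (SE, 18 pairs) between library medians. Mitochondrial transcripts and their copies took more of the adjacent kidney CPM, but with CPM recomputed without them the difference was 0.158 ± 0.0626 (SE), so they may account for part of it and are argued against as the whole cause. The lower depth of adjacent kidney libraries stays open: over the 11 deeper pairs the difference was 0.242 ± 0.158 (SE), within 2 SE both of 0 and of the full value. A true difference between the tissues stays open too, as untested.

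The second pattern is the rise of chondroitin and dermatan sulfate synthesis genes. The general rise of genes in tumour CPM is argued against as the whole cause, since the list kept 0.619 ± 0.127 (SE, 18 pairs) after centring, down from 1.01 ± 0.212. More endothelial and macrophage RNA in the tumour pieces may contribute. Fibroblast and pericyte markers were not higher on this scale, with a centred list mean of -0.12. The centred pair differences were regressed on those of these 3 marker lists. There the intercept was 0.366 ± 0.182 (SE), and the marker lists took an R squared of 0.697. That intercept passed the bound set before the result was seen, 2 SE or 0.365, by a margin too small to decide, and its 95% interval with 14 residual degrees of freedom, -0.0253 to 0.758, holds 0. Noise in the marker lists also raises such an intercept, so tumour cells and other cells as the source cannot be told apart here.

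The third pattern is CA9 in adjacent kidney, where the lowest library stood at 0.99 log2 CPM and 1 library, at 7.18, lay within the tumour range, the highest of the others being 4.83. Reads of other libraries assigned to adjacent kidney libraries may explain low levels, but the relation of CA9 to depth, rho = -0.455 (permutation p = 0.0594, 18 libraries; Pearson r = -0.397 with log2 depth, p = 0.101), missed the threshold, and without the 2 libraries of most extreme depth rho was -0.550 (p = 0.0293), so this stays open. A swap of the library at 7.18 with its own tumour library is argued against as the source of this level. That tumour library had 6.92, above every other adjacent kidney library (highest 4.83). A swap would thus still leave CA9 at a tumour level in the adjacent piece. With both values so high, CA9 alone cannot tell whether the labels were swapped. Tumour tissue in the adjacent piece cannot be told apart from other sources: the hypoxia target list of that library stood at 6.79, above the other adjacent libraries (highest 5.59) and inside the tumour range (5.58 to 7.39), while its proximal tubule markers, at 6.13, and loop markers, at 4.78, stayed within the adjacent kidney range. In the tumour libraries CA9 was lowest at 1.82, in the doubted pair 16, whose adjacent kidney library had 4.04. That tumour library was also the shallowest of the tumours, at 2.54 M reads. Whether the labels of pair 16 were swapped was not tested.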
